A study of Homo sapiens with 4 samples.

How the data were processed

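RNA was measured by polyadenylated-RNA sequencing in 4 libraries of LASCPC-01 cells, 2 treated with PBS and 2 with ketotifen, all labelled day 3. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a stranded mRNA kit, and paired-end reads were generated on an Illumina instrument. The submitters' processing notes name fastp, HISAT2, HTSeq and the build GRCh38, without versions or roles. The gene annotation, the gene lengths, the total used for scaling and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated.

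The deposited table holds one FPKM value (fragments scaled by gene length and library total) per gene and library, as the authors made it, for 16376 genes named by symbol. No mitochondrially encoded gene is among these rows. The columns name their group and carry the letters A and B. These letters were not matched to the replicate numbers of the labels, so libraries are called A and B within each group and are not paired across groups. Nothing in the labels says whether the 2 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

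FPKM values are not counts, so the main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were tested (10586 genes), the test was two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, ketotifen minus PBS, and understate changes of genes with low values. An exact permutation test on a single gene cannot go below p = 0.333 with 2 against 2 libraries, so no such test was made.

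The depth is not stated, but the values are steps. In each gene they are whole multiples of what 1 read is worth, which gives the relative depth of the libraries (Python 3.11.15). Relative to PBS library A, PBS library B was 1.06 times, ketotifen library A 1.12 times and ketotifen library B 1.03 times as deep. With these ratios, whole read numbers, up to a common factor per gene, were recovered for 99.8% of the tested genes (10567 genes). A value was accepted as whole within the rounding error of the 9 printed decimals, where that error stayed under 0.05 reads. Of 500 decoy genes whose values had been multiplied by random factors, 0 gave whole reads. On 1975 simulated genes, all were recovered, and in 91.9% the common factor was 1. The recovered reads summed to 29143590 and 30853538 for the PBS libraries and to 32490291 and 29895469 for the ketotifen libraries, with a median of 1476 reads per library and tested gene. These sums are lower bounds where a common factor remains. limma's voom was run on the recovered reads as an added alternative, since these are reads inferred from the authors' FPKM values.

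Both methods were tested on simulated data with the read numbers and library sizes of this comparison and a spread taken from it. Among 10567 simulated genes 200 were changed, and 10533 of the 10567 passed the filter. The test on FPKM recovered 30.6% of changes of 0.3 on the log2 scale, 92.0% of changes of 0.5 and all larger ones, with 12 false calls. Voom recovered 46.9%, 96.0% and all larger ones, with 11 false calls. The simulated spread was limma's estimate for each gene on log2(FPKM + 1), with read sampling added to it. That estimate already holds read sampling, so the simulated spread is not exactly that of the data. It was independent between genes, and changes of 1 and 2 were among those planted. Shifts shared by many genes were not simulated. The near equal results of the methods are unlike the data, where limma called 13 genes and voom 700. These figures may therefore not carry over.

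The 36 gene lists were fixed before the data were examined. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists. Camera was run with its variance trend. Camera with a correlation estimated per list and the rotation test fry were alternatives. Chosen after the data were seen, a one-sided Fisher's exact test compared the called genes with each list, adjusted over 58 list and direction combinations per tool, with all tested genes as background.

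The rule for named genes was also fixed beforehand. It takes the 12 largest rises and 12 largest falls among called genes with non-overlapping groups and a mean of at least 5 FPKM, 14 genes of the study's question, and the 3 members of each list with the smallest p. It gave 6 falls and no rise, and some of the genes it takes are not reported here. The called genes that no part of the rule takes, genes named from voom alone, and GAPDH and PGK1 were chosen after their values were seen.

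Alternatives planned before the data were examined were other pseudocounts (0.1 and 5), no filter and a mean of at least 5 FPKM, 3 other scalings, limma without trend, a minimum log2 fold of 1, the other list tests, and each library left out in turn. Added after the data were seen were voom, voom with quantile normalization, voom with an estimated correlation for the lists, a pseudocount of 0.5, camera without a variance trend, and a correction for transcript length and GC content. Length and GC content came from the longest coding transcript in GENCODE 29 (GRCh38), matched by symbol or older symbol for 99.7% of tested genes. Gene coordinates also come from GENCODE 29, which may not be the authors' annotation.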

Results

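LASCPC-01 is a human neuroendocrine prostate cancer line, made by transforming benign prostate epithelium with N-Myc and activated AKT1. Ketotifen is an H1 antihistamine and mast cell stabiliser, proposed in the series title as a treatment for this cancer. Gene expression was compared between 2 ketotifen and 2 PBS libraries at day 3. Group values are mean FPKM ± SD with n = 2 libraries throughout. Recovered reads ranged from 29143590 to 32490291 per library. The ketotifen libraries were the most alike (r = 0.998 over log2 values, across genes), and the PBS libraries correlated at r = 0.996. PBS library B stood farthest from the ketotifen libraries, with r = 0.993 and 0.994 against them, where PBS library A had 0.996 against each. Within both groups the libraries differed by more than read sampling, with a chi-square per gene of 9.98 for PBS and 4.65 for ketotifen where sampling alone gives about 1, so none was counted as a repeated copy of another. This does not tell separate cultures from technical replicates. By the same measure PBS library A lay about as far from ketotifen libraries A (10.7) and B (9.64) as from PBS library B. For PBS library B the values against ketotifen libraries A and B were 26.7 and 21.9.

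At the main settings 13 genes differed between ketotifen and PBS past the threshold. With ketotifen 12 of them were lower, a balance that some other settings did not keep. The largest fall among called genes with a mean of at least 5 FPKM was in ALDOC, the brain-type isoform of the glycolytic enzyme aldolase, from 14.0 ± 0.451 to 6.62 ± 1.37 FPKM. BNIP3, a mitophagy receptor induced in low oxygen, fell from 92.3 ± 6.58 to 60.9 ± 2.06 FPKM, and BHLHE40, a transcriptional repressor also induced in low oxygen, from 19.8 ± 0.362 to 11.3 ± 1.31 FPKM. NDUFA4L2, a mitochondrial protein induced in low oxygen, fell from 127 ± 2.29 to 89.7 ± 6.96 FPKM. P4HA1, a collagen prolyl hydroxylase subunit, fell from 19.4 ± 0.159 to 13.9 ± 0.286 FPKM, and FUT11, a fucosyltransferase family member, from 16.1 ± 0.411 to 11.3 ± 0.0349 FPKM. On the log2(FPKM + 1) scale the falls were -0.99 ± 0.11 (SE) for ALDOC, -0.77 ± 0.08 for BHLHE40, -0.59 ± 0.06 for BNIP3, -0.49 ± 0.06 for NDUFA4L2, -0.47 ± 0.06 for FUT11 and -0.45 ± 0.06 for P4HA1. The limma adjusted p was 0.0284 for the first 3 of these, 0.0437 for NDUFA4L2 and 0.0426 for FUT11 and P4HA1. In GRCh38, P4HA1 (73007217 to 73096974), FUT11 (73772291 to 73780251) and BNIP3 (131966455 to 131982013) lie on chromosome 10. ALDOC lies on chromosome 17 (28573115 to 28577264), BHLHE40 on chromosome 3 (4979116 to 4985323) and NDUFA4L2 on chromosome 12 (57234903 to 57240715).

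The other genes past the threshold had lower expression levels. NDRG1, a stress-response gene induced by hypoxia and by androgen, fell from 5.58 ± 0.327 to 2.12 ± 0.266 FPKM (log2 change -1.08 ± 0.09 SE, limma adjusted p = 0.0112). VIM, the mesenchymal intermediate filament vimentin, fell from 5.44 ± 0.115 to 3.08 ± 0.0975 FPKM, and FN1, the matrix protein fibronectin, from 2.88 ± 0.594 to 1.03 ± 0.0891 FPKM. DBH, the enzyme that makes noradrenaline from dopamine, fell from 6.01 ± 0.761 to 2.59 ± 0.41 FPKM. CABP7, a calcium-binding protein, fell from 5.20 ± 0.61 to 2.34 ± 0.38 FPKM, and WNT10A, a Wnt ligand, from 2.25 ± 0.154 to 0.715 ± 0.0205 FPKM. DBH, CABP7 and WNT10A lay outside the rule for named genes. The single rise was in the row ASMTL-2, from 0.228 ± 0.0491 to 3.92 ± 1.31 FPKM, and it too lay outside the rule. ASMTL is a pseudoautosomal gene with identical copies on the X and Y chromosomes. From its symbol alone, ASMTL-2 is assumed here to be a copy of it. The table has another row, ASMTL, listed at 0 in 3 of the 4 libraries, and which copy the reads came from is uncertain.

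**Figure D1:**
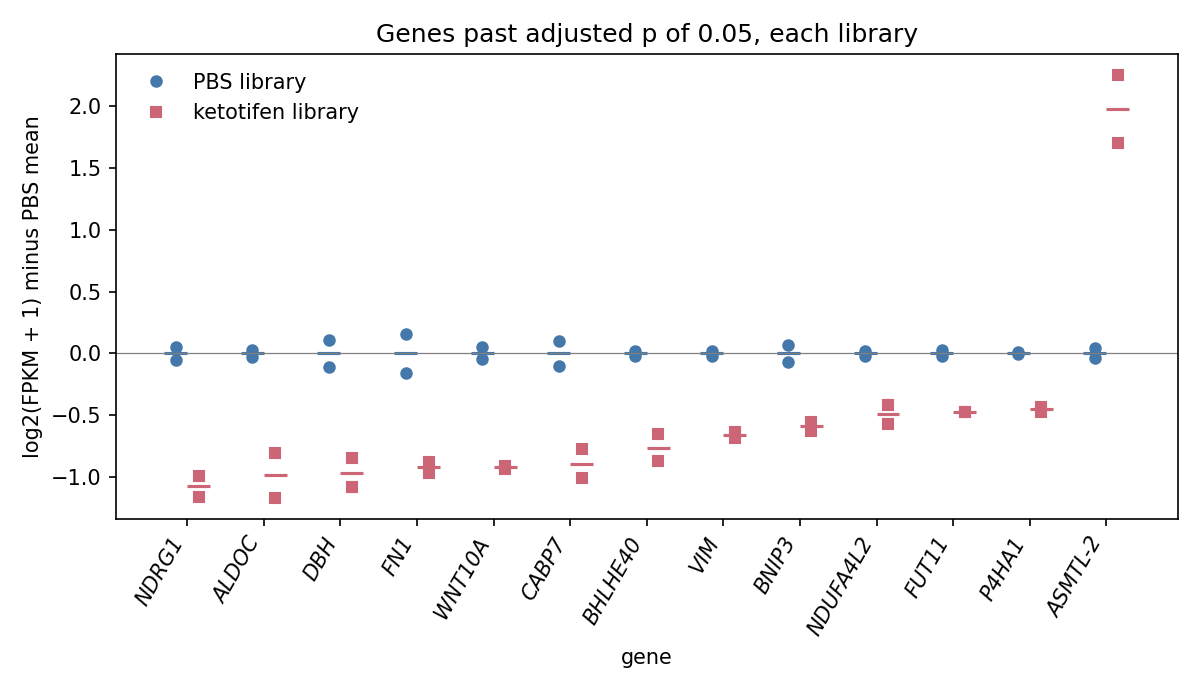
Each library's log2(FPKM + 1) minus the PBS mean for the 13 genes with an adjusted p under 0.05. Circles are PBS libraries, squares are ketotifen libraries and short lines are group means; 12 genes lie below the PBS mean in both ketotifen libraries and ASMTL-2 lies above it.

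In total 1 gene rose and 12 fell among 10586 tested (limma, adjusted p under 0.05), and 2157 genes had an unadjusted p under 0.05 where 529 would be expected by chance. Voom on the recovered reads called 362 higher and 338 lower, including all 13. With a mean of at least 5 FPKM the limma test called 15 higher and 12 lower among 7723 genes. After median ratio scaling, and after quantile normalization, 1 rose and 2 fell, and with no filter none passed (2295 genes at an unadjusted p under 0.05). The number of calls depended on single libraries. It was 1058 higher and 867 lower without PBS library A, 249 and 156 without PBS library B, 6 and 23 without ketotifen library A, and 3 and 5 without ketotifen library B. The 13 genes kept their direction in each of these fits. This was fixed in advance, since their groups do not overlap. The median absolute log2 change over all tested genes was 0.09.

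Genes of glycolysis and of the hypoxia response were lower with ketotifen as a list. Of 27 measured members 3 fell (ALDOC, BNIP3 and NDRG1), none rose and 24 did not pass; adjusted over the list alone, 13 fell. The median change was -0.16, and camera placed the list below other genes (adjusted p = 2.47e-07), though the call was lost with an estimated correlation (adjusted p = 0.568) and in fry (adjusted p = 0.148). The 3 called members compare with 0.0306 expected among the 12 genes that fell (Fisher's exact test, adjusted p = 0.000186). That test treats genes as independent, while the correlation estimated between members of this list was 0.297, so its p-value is too small. Voom called 12 of 25 members lower and none higher. Among these, VEGFA, the angiogenic growth factor, went from 38.2 ± 0.201 to 29.05 ± 1.31 FPKM (voom adjusted p = 0.00102, limma adjusted p = 0.0713). PFKFB4, a regulator of glycolysis, went from 15.5 ± 0.658 to 10.7 ± 1.47 FPKM, and PDK1, which inhibits pyruvate dehydrogenase, from 12.2 ± 1.08 to 8.62 ± 1.38 FPKM. The enzymes ALDOA, LDHA and PKM were also among the 12. GAPDH had 2829 ± 65.3 FPKM with PBS and 2856 ± 23.2 with ketotifen, and PGK1 had 119 ± 13.5 and 122 ± 10.4 FPKM.

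Mesenchymal genes were also lower as a list. Of 6 measured members 2 fell (VIM and FN1), none rose and 4 did not pass, and 3 fell when adjusted over the list alone. The median change was -0.22 (camera adjusted p = 0.028), and the call was lost with an estimated correlation (adjusted p = 0.568) in camera after rescaling each library to an equal sum (adjusted p = 0.0534), in camera with no filter (median -0.094, adjusted p = 0.0624) and in fry (adjusted p = 0.0813). SNAI1, a repressor of epithelial genes, had 47.5 ± 4.74 FPKM with PBS and 39.9 ± 4.16 with ketotifen (limma adjusted p = 0.192). Epithelial adhesion genes did not pass as a list (16 measured, 0 past the threshold, median -0.03, camera adjusted p = 0.238), but did after quantile normalization (median -0.077, camera adjusted p = 0.0433). CDH1, or E-cadherin, had 88.5 ± 3.96 FPKM with PBS and 77.2 ± 0.307 with ketotifen (limma adjusted p = 0.136, voom adjusted p = 0.0231). Voom called 2 of the 16 epithelial adhesion genes lower, CDH1 and TJP1, and 0 higher. Fibroblast markers had 1 measured member, COL1A1, with 2.64 ± 0.15 FPKM under PBS and 2.17 ± 0.316 under ketotifen, and endothelial markers had none.

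Cytosolic ribosomal protein genes were higher as a list. None of the 28 measured members passed over all genes, and 16 rose when adjusted over the list alone, with a median change of 0.19 (camera adjusted p = 5.38e-10; adjusted p = 0.568 with an estimated correlation and 0.226 in fry). The list stayed past the threshold with a median of 0.066 after quantile normalization (camera adjusted p = 0.0267), 0.11 after the length and GC correction and 0.12 without PBS library B. RPS16 had 996 ± 111 FPKM with PBS and 1298 ± 23.5 with ketotifen, and RPS27A had 243 ± 30.5 and 314 ± 13.8 FPKM. Nuclear genes of oxidative phosphorylation had 27 measured members, none past the threshold and 7 risen when adjusted over the list alone. Their median change was 0.17 (camera adjusted p = 1.30e-06; adjusted p = 0.577 with an estimated correlation and 0.414 in fry), and 0.11 after quantile normalization, 0.095 without PBS library B and 0.11 without ketotifen library A, each still past the threshold. NDUFB8, a complex I subunit, had 122 ± 11.5 and 156 ± 4.34 FPKM, and SDHD, a complex II subunit, had 44.9 ± 5.04 and 58.7 ± 1.19 FPKM. Voom called 16 of 24 ribosomal protein genes and 11 of 27 oxidative phosphorylation genes higher, and none lower. Over both lists the median difference between the PBS libraries themselves was -0.15 (B minus A), against 0.17 between the groups. Between the ketotifen libraries it was -0.039 (B minus A).

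DNA replication genes and MYC targets were also higher as lists at the main settings, with smaller medians. The difference from the lists above was not tested. Of 28 G1/S and DNA replication genes none passed, with a median change of 0.08 (camera adjusted p = 0.00252; adjusted p = 0.568 with an estimated correlation and 0.0644 in fry), or 0.031 after rescaling each library to an equal sum (camera adjusted p = 0.0141). FEN1, the flap endonuclease, had 80.4 ± 8.2 FPKM with PBS and 94.6 ± 3.22 with ketotifen, and MCM7, a subunit of the replicative helicase, had 143 ± 5.83 and 158 ± 3.32 FPKM. Of 23 MYC target and ribosome biogenesis genes none passed, with a median of 0.06 (camera adjusted p = 0.0028; adjusted p = 0.568 with an estimated correlation and 0.143 in fry). The median was 0.0058 after rescaling to an equal sum, where the list still passed (camera adjusted p = 0.0141). That rescaling moved the median of all tested genes from -0.018 to -0.069. Without ketotifen library A the median of the list was 0.083. The camera call was lost without ketotifen library B, and also after quantile normalization (camera adjusted p = 0.226). The G2/M list did not pass (28 measured, median -0.04, camera adjusted p = 0.672), nor did p53 targets (21 measured, median -0.02, adjusted p = 0.925; adjusted over the list alone 3 rose and 3 fell) or apoptosis regulators (23 measured, median 0.02, adjusted p = 0.406). In the G2/M list voom called 2 members higher, CCNB1 and BIRC5, and none lower. CCNB1, a mitotic cyclin, had 149.7 ± 8.72 FPKM with PBS and 175 ± 1.15 with ketotifen (limma adjusted p = 0.118, voom adjusted p = 0.0132). Replication-dependent histones, which lack poly(A) tails and reflect RNA selection, had 8 measured members and a median of 0.11 (camera adjusted p = 0.162). The median was 0.16 without PBS library B, 0.060 without PBS library A and -0.054 after the length and GC correction.

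**Figure D2:**
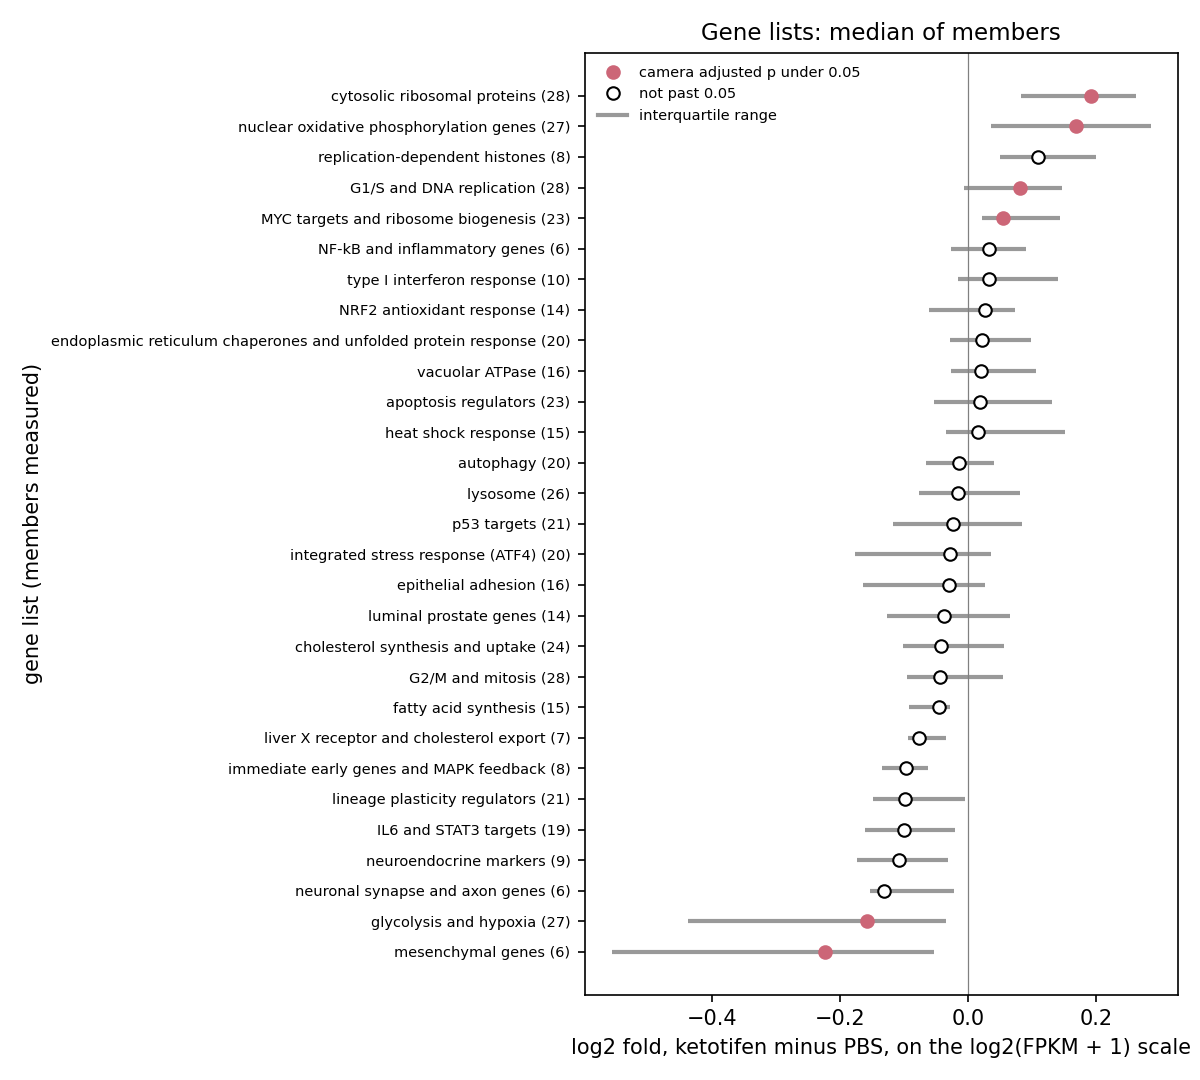
Median log2 change (ketotifen minus PBS, log2(FPKM + 1) scale) of the members of the 29 tested gene lists, with grey lines for the interquartile range of the members and the number measured in brackets. Filled points mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation, from mesenchymal genes at -0.22 to cytosolic ribosomal proteins at 0.19.

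Neuroendocrine identity genes, the question named in the title, did not pass as a list in camera at the main settings. Of 9 measured markers none passed over all genes, 2 fell when adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.196). It was -0.038 with no filter, -0.031 with a mean of at least 5 FPKM and -0.18 after rescaling each library to an equal sum. The self-contained test fry, which asks whether the genes move one way on balance, passed (adjusted p = 0.00503). The change was negative in 7 of the 9 markers and positive in 2. UCHL1, among the positive ones, had 446 ± 16.4 FPKM with PBS and 488 ± 2.42 with ketotifen (limma adjusted p = 0.226, voom adjusted p = 0.0907). INSM1, a neuroendocrine lineage factor, had 22.3 ± 0.856 FPKM with PBS and 20.8 ± 1.49 with ketotifen, a change of -0.10 with a 95% interval of -0.25 to 0.06. NCAM1, a neural adhesion molecule, had 51.6 ± 0.62 and 44.2 ± 0.355 FPKM (limma adjusted p = 0.107, voom adjusted p = 0.0105). ENO2, neuron-specific enolase, had 2.93 ± 0.24 and 1.83 ± 0.329 FPKM (limma adjusted p = 0.102, voom adjusted p = 0.044). SYP and CHGA, classic neuroendocrine markers, were low in these cells. SYP had 0.517 ± 0.109 FPKM with PBS and 0.42 ± 0.0581 with ketotifen, and CHGA had 0 to 7 reads per library. Neither was tested. MYCN had 378 ± 11.9 and 329 ± 3.85 FPKM (limma adjusted p = 0.123, voom adjusted p = 0.0122). The line was made with N-Myc, and reads of an introduced copy were not told apart from those of the cells' own gene. The lineage plasticity list (21 measured, none past the threshold, 1 fallen when adjusted over the list alone) had a median of -0.10 (camera adjusted p = 0.0956), or -0.062 without PBS library B and -0.15 after rescaling to an equal sum. It passed after quantile normalization of the FPKM (median -0.11, camera adjusted p = 0.0433) and of the voom values (median -0.088, camera adjusted p = 0.0403). Voom called 3 of its members lower (MYCN, NOTCH2 and PEG10) and 1 higher, HES6, which had 186 ± 27 FPKM with PBS and 228 ± 2.04 with ketotifen (voom adjusted p = 0.012). Neuronal synapse genes (6 measured) had a median of -0.13 (camera adjusted p = 0.325).

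Of 14 measured luminal prostate genes 1 fell, NDRG1, which is also in the hypoxia list, and 13 did not pass (median -0.04, camera adjusted p = 0.347; median -0.090 to 0.044 over the other settings, none past the threshold). KLK3, which encodes prostate-specific antigen, had 10 and 2 reads in the PBS libraries and 19 and 11 in the ketotifen libraries. It did not reach the filter, and at these read numbers no difference was tested. The basal prostate epithelium list had 3 measured members, none past the threshold and 2 fallen when adjusted over the list alone, too few for a list test. With no filter it was tested and lay below other genes (median -0.094, camera adjusted p = 0.00361). Of the 3, ITGA6, an integrin, had 14.4 ± 0.516 FPKM with PBS and 12.3 ± 0.526 with ketotifen.

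IL6 and STAT3 targets did not pass as a list at the main settings, though they did with no filter (camera adjusted p = 0.0341) and after quantile normalization (camera adjusted p = 0.0444). Of 19 measured members none passed over all genes. Adjusted over the list alone 1 rose, BIRC5, an inhibitor of apoptosis, and 1 fell, VEGFA. The median was -0.10 (camera adjusted p = 0.0841), or -0.047 without PBS library B, -0.15 without ketotifen library B and -0.17 after rescaling to an equal sum. STAT3 had 26.4 ± 0.507 FPKM with PBS and 26.1 ± 0.836 with ketotifen, a change of -0.01 with a 95% interval of -0.14 to 0.12. IL6R, the IL6 receptor, had 10.5 ± 1.15 and 9.72 ± 1.56 FPKM, and SOCS3, the feedback inhibitor induced by STAT3, had 14 and 31 reads against 16 and 34. IL6 itself was not analysed here. HRH1, the receptor that ketotifen blocks, was listed at 0 in 3 libraries and at 0.00646 FPKM in PBS library A. Of the amine receptor list only the serotonin receptor HTR2C was measured, with 3.09 ± 0.165 and 3.13 ± 0.0108 FPKM. Mast cell markers had 3 measured members and immune cell markers 2, none past the threshold.

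Lists chosen because ketotifen is an amphiphilic amine, a class that can accumulate in lysosomes, did not pass at the main settings. The median was -0.02 for 26 lysosomal genes (camera adjusted p = 0.672), 0.02 for 16 vacuolar ATPase genes (adjusted p = 0.311), -0.01 for 20 autophagy genes (adjusted p = 0.672), -0.04 for 24 cholesterol genes (adjusted p = 0.608), -0.05 for 15 fatty acid synthesis genes (adjusted p = 0.105) and -0.08 for 7 liver X receptor genes (adjusted p = 0.452). The lysosomal list's mean was 0.00 and camera placed it upward, opposite in sign to its median. Fatty acid synthesis genes passed after quantile normalization (median -0.079, camera adjusted p = 0.032). Adjusted over the list alone, 1 cholesterol gene rose and 1 fell, 1 fatty acid gene fell, 1 vacuolar ATPase gene rose and 2 autophagy genes fell; none of these passed over all genes. SCD, stearoyl-CoA desaturase, had 167 ± 2.4 FPKM with PBS and 144 ± 2.92 with ketotifen (limma adjusted p = 0.11, voom adjusted p = 0.00836). Stress lists did not pass there either, with no member past the threshold over all genes. Endoplasmic reticulum chaperones (20 measured) had a median of 0.02 (adjusted p = 0.128), ATF4 targets (20 measured) -0.03 (adjusted p = 0.311), heat shock genes (15 measured) 0.02 (adjusted p = 0.133) and NRF2 targets (14 measured) 0.03 (adjusted p = 0.672) by camera. Adjusted over the list alone, 2 chaperones and 2 heat shock genes rose, and 2 ATF4 targets and 1 immediate early gene fell. Interferon genes (10 measured) had a median of 0.03 (adjusted p = 0.325), NF-kB genes (6 measured) 0.03 (adjusted p = 0.599) and immediate early genes (8 measured) -0.10 (adjusted p = 0.105) by camera. Without PBS library B the median was 0.063 for chaperones, 0.047 for heat shock genes and -0.10 for immediate early genes. Without PBS library A it was -0.011, 0.025 and -0.11 in the same order. Whether these lists passed in the fits without a PBS library is not given here, since the PBS group then rests on a single library. After quantile normalization it was -0.016, -0.036 and -0.10, with no camera call. Heat shock genes had a median of 0.015 without ketotifen library A. Immediate early genes passed in camera with a mean of at least 5 FPKM (median -0.11, adjusted p = 0.0156). HSPA5, the main chaperone of the endoplasmic reticulum, had 169 ± 4.22 and 200 ± 4.08 FPKM (limma adjusted p = 0.1003, voom adjusted p = 0.0037).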

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

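Voom, the length and GC correction, a pseudocount of 0.5 and camera without a variance trend were added after the data were seen. No paired analysis was possible because the columns carry letters that could not be matched to the replicate numbers of the labels; a block on the letters themselves was not run, since nothing says that a letter pairs libraries. The count of risen genes (1 as reported) was 0 with no filter, 15 with a mean of at least 5 FPKM, 362 by voom, 323 by voom with quantile normalization, 0 after the length and GC correction, for which ASMTL-2 had no annotated length (1905 genes at an unadjusted p under 0.05 in limma), and 3 to 1058 with each library left out. The count of fallen genes (12 as reported) was 0 with no filter, where 2295 genes had an unadjusted p under 0.05 in limma. It was 2 after median ratio scaling and after quantile normalization, 3 without the intensity trend, 338 by voom, 252 by voom with quantile normalization, 1 with a log2 fold of at least 1, and 5 to 867 with each library left out. Leaving out a library leaves a group of 1 that is assumed to vary like the other group, on 1 residual degree of freedom. It cannot turn the direction of a gene whose groups do not overlap, as in all 13 called genes. The cause of the other shifts was not tested. The share of rises among calls was 7.69% as reported, 55.6% with a mean of at least 5 FPKM, 33.3% after median ratio scaling and after quantile normalization, 25% without trend, 51.7% by voom and 56.2% by voom with quantile normalization. Of the 13 called genes, 12 remained at a pseudocount of 5, 11 of 12 tested after the length and GC correction, 6 of 6 tested with a mean of at least 5 FPKM, 4 without trend, 3 each after median ratio scaling and quantile normalization and 0 with no filter, and those tested kept their direction under all alternatives run. The lists called higher (4 as reported) were 0 with an estimated correlation (on FPKM with or without a variance trend, and on voom values), 0 by fry, and 3 to 7 with each library left out. The lists called lower (2 as reported) were 0 with an estimated correlation in the same 3 fits, 1 by fry (the neuroendocrine markers), 1 after rescaling libraries to an equal sum and 7 after quantile normalization; they were 2 to 3 with each library left out. Neuroendocrine markers passed with a median of -0.11 after quantile normalization (camera adjusted p = 0.0433) and by fry, with the same median of -0.11; over all their alternatives the median ran from -0.18 to -0.031 and adjusted p from 0.00503 to 0.838. IL6 and STAT3 targets passed with a median of -0.098 with no filter (camera adjusted p = 0.0341) and -0.094 after quantile normalization (adjusted p = 0.0444), in a range up to 0.596. No called gene or list changed direction; among those past no threshold in either fit, list directions flipped in 16 cases and gene directions in 15. Depth limits KLK3, CHGA and SOCS3, at 0 to 34 reads per library.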

Other observations

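The tests in this part on splits of the libraries and on culture conditions were chosen after the results were seen, as were voom, the length and GC correction and the genes named from voom. By voom, several genes outside the fixed lists moved with ketotifen. STC1, a secreted glycoprotein hormone, went from 1.85 ± 0.241 to 0.514 ± 0.348 FPKM (voom log2 change -2.00, adjusted p = 0.00143), and SLC16A3, the lactate exporter MCT4, from 2.48 ± 0.0716 to 0.991 ± 0.402 FPKM (-1.36, adjusted p = 0.00265). MUC6, a gel-forming mucin, went from 30.4 ± 3.5 to 20.4 ± 0.963 FPKM (-0.57, adjusted p = 7.92e-05), and KCNN3, a calcium-activated potassium channel, from 35.0 ± 0.709 to 28.5 ± 0.806 FPKM (-0.29, adjusted p = 0.00208). MAGEA3, a cancer-testis antigen with close paralogs, went from 35.2 ± 0.671 to 45.6 ± 1.57 FPKM (0.38, adjusted p = 0.00195). The centromere genes CENPM (17.8 ± 0.217 to 24.5 ± 1.32 FPKM) and CENPW (13.2 ± 0.776 to 18.2 ± 0.71 FPKM) were also higher by voom. None of these passed the limma test on FPKM.

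The glycolysis and hypoxia list was lower with ketotifen, with a median log2 change of -0.16. Length and GC bias is argued against, since the median after correction was -0.15. One aberrant library is also argued against, since the weakest median with any library left out was -0.13. Oxygen supply or cell density that differed between the cultures for a reason other than the drug stays open. The PBS libraries differed from each other by -0.063 (B minus A) in this list, but no library separates culture from treatment, so these cannot be told apart, and a direct effect of ketotifen remains an untested hypothesis.

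Ribosomal protein and oxidative phosphorylation genes were higher with ketotifen as lists, with a median of 0.17 over 55 members. No member passed over all genes, and both list calls were lost with an estimated correlation and in fry. Many of these genes are short, and changes between the groups fell with transcript length across all tested genes (Spearman rho -0.35, genes not being independent replicates). Length and GC bias as the whole cause is argued against, since the median after correction was 0.13 (0.11 against 0.19 for the ribosomal proteins alone). Spread between cultures without treatment stays open. The same members differed by -0.15 between the PBS libraries (B minus A), close to the shift between the groups. Between the ketotifen libraries they differed by -0.039 (B minus A). The ketotifen shift was 0.11 without PBS library B and 0.23 without PBS library A. A candidate explanation is that PBS library B, the PBS library farther from the ketotifen libraries, carries part of this shift.

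ASMTL-2 rose with ketotifen on 16 and 23 reads in the PBS libraries and 449 and 255 in the ketotifen libraries. If ASMTL-2 is a copy of ASMTL, which only its symbol shows, a move of counted reads out of the ASMTL row is argued against. That row was at 0 in both PBS libraries, so the summed FPKM of both rows rose by 100.3% of the rise of ASMTL-2. Reads shared by identical copies and left uncounted cannot be seen here. A change in how such reads were assigned therefore stays open. Reads from a neighbouring or overlapping transcript were not tested, and the treatment stays open.

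The 4 libraries can be split 2 against 2 in 3 ways, too few for a share under 0.05. The real split called 13 genes by limma and 1 of the 3 splits reached that number; the highest of the other splits called 0, with 174 and 126 genes at an unadjusted p under 0.05 against 2157 in the real split. By voom the real split called 700 and the others 0. In the other splits each side mixes the groups, so any difference between the groups widens the spread there. Their 174 and 126 genes, under the 529 expected by chance, therefore give no baseline.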
